A study of Mus musculus with 18 samples.

How the data were processed

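The samples were RNA libraries of purified mouse brain microglia, 18 in all, labelled by sex and by Chd8 genotype (KO or WT). The labels give 4 libraries of female KO, 4 of female WT, 5 of male KO and 5 of male WT, and a replicate number that differs for each library. They name no pairing, batch or litter, so whether any libraries were paired is not known. The labels carry a prefix (HX) that they do not explain. Per the labels' protocols, RNA was isolated with a Qiagen RNeasy kit, 30 ng per sample was barcoded during reverse transcription, samples were pooled, amplified linearly by T7 in vitro transcription and converted into libraries by a bulk form of MARS-seq that targets polyadenylated 3' ends. Which samples shared a pool is not stated.

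The authors deposited 2 tables of whole-number counts per gene, with reads counted before correction for UMIs in one and UMI-corrected counts in the other, and neither was scaled for depth. The submitters' processing notes name cutadapt, STAR and HTSeq without versions and the genome build mm10. The annotation release, the read filters, the strand setting and the method of UMI correction are not given in the sources used here. In no cell did the UMI-corrected count exceed the read count. Each table held 34 columns of libraries, of which 16 match no sample used here and were not used in any step. Each table listed 55414 Ensembl gene identifiers, of which 52081 were given symbols and coordinates from the GENCODE M21 annotation of GRCm38, the same assembly as mm10. Of the others, 3281 are absent from that release. In each library at least 99.8% of UMIs fell on identifiers with a symbol. Counting by 3' tags can merge overlapping genes and split reads between near-identical copies, so values of gene families such as ribosomal proteins, Gapdh and haemoglobins are uncertain to that extent.

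UMI-corrected counts were the main measurement. They totalled 435838 to 9149144 per library, a 21.0-fold range, against 2405764 to 17313836 reads. Intervals computed from counts cover counting error only. Genes were filtered with filterByExpr by group, which left 10948 genes, libraries were scaled by TMM, and a quasi-likelihood negative binomial model with 1 mean per group was fitted to all 18 libraries together in edgeR 4.0.16 (R 4.3.3), with a common biological coefficient of variation of 17.8%. Contrasts were KO against WT in females, in males and averaged over both with equal weight, the difference of the KO effect between sexes (female minus male), and male against female in WT and in KO. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. The SE of a log2 fold change was its size divided by the square root of the F statistic. CPM values of single genes were scaled by TMM. Summed CPM of marker lists, and CPM of Y-linked genes, were scaled by the library total alone.

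Gene lists were tested with limma 3.58.1 camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists within a contrast. Of 32 lists, 29 had at least 4 tested members. The lists were microglial identity, disease-associated microglia, type I interferon response, antigen presentation, inflammatory cytokines, immediate early and dissociation response, proliferation, p53 targets, Wnt and beta-catenin targets, CHD remodelers, histone methyltransferase complexes and CTCF, cytosolic ribosomal proteins, nuclear oxidative phosphorylation, mitochondrially encoded transcripts, complement and phagocytosis, lysosome and autophagy, cholesterol synthesis, glycolysis, TGF-beta signalling, stress response (integrated stress and unfolded protein response), Y-linked genes, X-linked female-biased genes, and markers of neurons, astrocytes, oligodendrocyte lineage, endothelial and mural cells, border-associated macrophages, monocytes, neutrophils, lymphocytes, erythroid cells and choroid plexus with ependyma. Y-linked genes (3 tested members), lymphocytes (3) and choroid plexus (2) were too short to test. Some markers of other cells are also expressed in these libraries at 10 CPM or more in every group, which held for 1 of 8 neuronal, 2 of 9 astrocyte, 4 of 8 oligodendrocyte lineage, 3 of 15 border-associated macrophage, 3 of 10 monocyte and 8 of 12 neutrophil markers, and none of these markers was in another list. Lists, contrasts, tests and the first set of alternatives were fixed before the data were examined.

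The genes named were Chd8, per KO contrast the 10 called genes with the largest rise and the 10 with the largest fall among those with a mean log2 CPM of at least 3, without predicted genes and pseudogenes, up to 4 called members of each list with the lowest p, for the sex contrasts the sex-linked lists and the 5 largest other genes per direction, and the genes whose KO effect differed between sexes. Where fewer than 5 genes passed in a direction, those of lowest p were added up to 5 as values that did not pass. This gave 243 distinct genes, of which the text describes a part.

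Per-library measures (10 sums of other-cell markers, total UMI count, reads per UMI and detected genes) were compared between KO and WT within each sex by exact two-sided permutation tests (scipy 1.17.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3), with Benjamini-Hochberg adjustment over 26 tests. Figures were drawn with matplotlib 3.10.9. Replicate pairs were checked for copies by a chi-square comparison of their counts. Alternatives were size factors of DESeq2 in place of TMM, no filter and a stricter filter of at least 10 counts in every library of a group, the table without UMI correction, the DESeq2 1.42.0 test, a fit of only the groups compared, the range of the replicate numbers, 1 surrogate variable (sva 3.50.0) or log2 of the total count as a covariate, a 2-fold minimum, and leaving out each library in turn. A further 9 alternatives were chosen after seeing the data, because libraries fell into 3 ranges of reads per UMI that the labels do not mention and because some libraries were shallow or rich in neural transcripts. The result for 1 gene is not reported here.

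The fits were tested on counts simulated with the depths and means of these libraries. For KO in females (10629 genes), 16%, 46% and 84% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered. Of the calls 6.80% were false. For males (10643 genes) the shares were 28%, 68% and 94%, with 5.84% of calls false. These shares need not hold here, as reads per UMI differed too.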

Results

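Microglia are the resident macrophages of the brain. They were purified from mice labelled as Chd8 knockout (KO) or wild type (WT), of both sexes, and their RNA was measured with a bulk form of MARS-seq, which counts 3' ends of polyadenylated RNA and marks each captured molecule with a unique molecular identifier (UMI). Chd8 encodes a chromatin remodeler of the CHD family and is a known autism risk gene. The labels do not say how many copies of Chd8 were altered, in which cells, or which exons were removed. The 18 libraries formed 4 groups, with 4 libraries of female KO, 4 of female WT, 5 of male KO and 5 of male WT.

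Depth differed between groups. The total UMI count of the female KO libraries was 435838, 3433078, 1919717 and 3117474 in replicates 33, 16, 1 and 7. In female WT it was 458075, 1319376, 1841384 and 1372425 in replicates 34, 39, 31 and 30. The male KO libraries held 4549562, 2704944, 2022957, 3231158 and 9149144 in replicates 36, 6, 9, 17 and 40, and the male WT libraries 3002838, 2785359, 2050624, 3441103 and 3170707 in replicates 13, 37, 10, 11 and 14. Detected genes numbered 12150 to 16580 in female KO, 12831 to 15587 in female WT, 16006 to 18768 in male KO and 14940 to 16380 in male WT. The number of sequenced reads per UMI fell into 3 separate ranges, of 1.79 to 1.89 (8 libraries), 2.94 to 3.12 (6 libraries) and 5.52 to 7.26 (4 libraries). The highest range held 3 of the 4 female WT libraries and 1 female KO library, and no male library. Every replicate pair of a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.80 to 13.3 over 32 pairs, so that no library was counted as a copy of another. P-values throughout measure the spread between these libraries, since the labels do not say that they came from separate animals or litters.

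**Figure D1:**
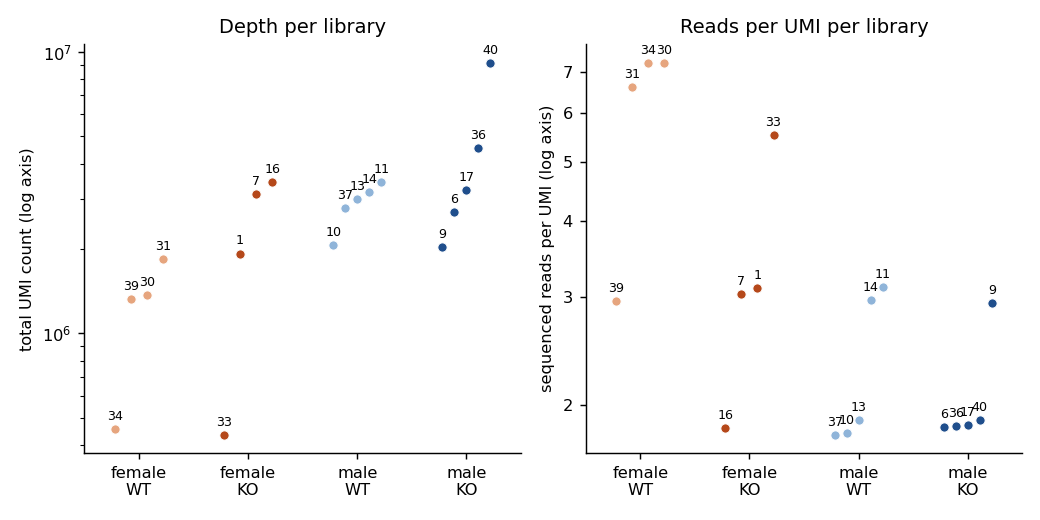
Total UMI count (left, log axis) and sequenced reads per UMI (right, log axis) of each of the 18 libraries, by group, with 1 point per library and its replicate number beside it. Female libraries reach from 435838 to 3433078 UMIs and male libraries from 2022957 to 9149144, and the 4 libraries with 5.52 or more reads per UMI are all female.

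Whether the labelled gene itself differed was asked first. Chd8 (ENSMUSG00000053754, chromosome 14, 52198151 to 52257780 on the minus strand of GRCm38) was measured at 104 ± 8.52 CPM (counts scaled to library size, mean ± SD, n = 5) in male KO and 152 ± 12.7 CPM (n = 5) in male WT. In females it was 123.2 ± 10.8 CPM (n = 4) in KO and 166 ± 24.3 CPM (n = 4) in WT. All 5 male KO libraries (96.4 to 116 CPM) lay below all 5 male WT libraries (135 to 167 CPM). Among females, WT replicate 39 (132 CPM) lay below KO replicate 33 (139 CPM), while the other libraries did not overlap. Chd8 fell in males, with a log2 fold change of -0.54 ± 0.10 (SE), 1.46-fold lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00171), and averaged over both sexes, with -0.49 ± 0.08 (edgeR adjusted p = 0.000413). The female log2 fold change of -0.44 ± 0.12 did not pass by itself (edgeR adjusted p = 0.0547), and the effects of the 2 sexes differed by 0.10 ± 0.16 (edgeR adjusted p = 0.934). A 3' tag outside the removed part of the gene would still be counted, so these levels do not check the KO label. The female test passed with DESeq2 (adjusted p = 0.0173), with 1 surrogate variable (edgeR adjusted p = 0.0177) and without KO replicate 33 or WT replicate 39 (edgeR adjusted p = 0.0196 and 0.0197), and over 25 alternatives its adjusted p ran from 0.0173 to 0.722. With the reads-per-UMI range as a covariate the female log2 fold change was -0.24. Chd8 in males no longer passed on read counts without UMI correction (edgeR adjusted p = 0.0753) or without male KO replicates 6, 9 and 17 (edgeR adjusted p = 0.0879), and passed in the other 24 of 26 alternatives, where the lowest adjusted p was 4.78e-06.

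**Figure D2:**
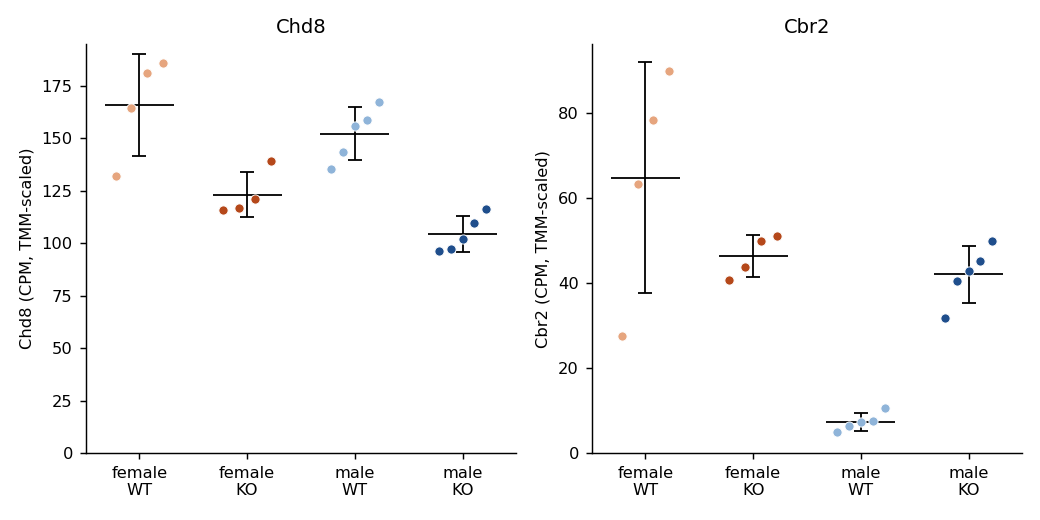
Chd8 (left) and Cbr2 (right) in CPM, scaled by TMM, in each library by group, with 1 point per library, bars at the group mean and error bars of 1 SD. The male KO points for Chd8 lie at 96.4 to 116 CPM, below the male WT points at 135 to 167 CPM, and the 5 male WT points for Cbr2 lie at 5.01 to 10.7 CPM, below the points of the other groups.

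Transcripts of other brain cells were measured in each library as summed CPM over marker lists. In males, KO libraries held 145 ± 79.5 CPM (mean ± SD, n = 5) of neuronal markers against 34.99 ± 6.00 CPM (n = 5) in WT, 4.14-fold higher. Astrocyte markers summed to 408 ± 113 against 171 ± 22.002 CPM, 2.39-fold higher. Oligodendrocyte lineage markers, of which Trf is also expressed outside that lineage, summed to 2166 ± 167 against 1687 ± 155 CPM, 1.28-fold higher. Markers of border-associated macrophages, which line vessels and meninges, summed to 273 ± 54.3 against 90.8 ± 18.8 CPM, 3.005-fold higher. Endothelial and mural markers summed to 598 ± 49.0 against 793 ± 32.1 CPM, 1.33-fold lower in KO, and most of this sum came from Bsg, which microglia also express. In each of these 5 sums all male KO libraries lay on 1 side of all male WT libraries (exact two-sided permutation test, p = 0.00794, the smallest p that 5 against 5 libraries can give, Benjamini-Hochberg adjusted p = 0.0413 over 26 tests). On read counts without UMI correction the oligodendrocyte lineage sum no longer passed (exact permutation test, adjusted p = 0.0794).

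The remaining sums did not pass in males. Lymphocyte markers were at 1217 ± 107 CPM in KO and 1023 ± 83.6 in WT (exact permutation test, adjusted p = 0.103), and erythroid markers at 282 ± 146 and 74.1 ± 67.2 CPM (exact permutation test, adjusted p = 0.118). Monocyte markers were at 96.8 ± 30.8 and 91.9 ± 15.1 CPM, neutrophil markers at 1142 ± 109 and 1373 ± 399 CPM, and choroid plexus and ependymal markers at 502 ± 284 and 669 ± 237 CPM. In females no single sum could pass, since 4 against 4 libraries give no p below 0.0286 before adjustment. Monocyte markers were at 234 ± 66.0 CPM (n = 4) in KO and 689 ± 280.0 CPM (n = 4) in WT (exact permutation test, p = 0.0571, adjusted p = 0.165), and neutrophil markers at 3142 ± 2019 and 8065 ± 6314 CPM (exact permutation test, p = 0.200, adjusted p = 0.371), where female WT replicate 30 alone held 16798 CPM. Female border-associated macrophage markers were at 291 ± 74.2 and 321 ± 85.6 CPM. Total UMI count, reads per UMI and detected genes did not pass between KO and WT in males.

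**Figure D3:**
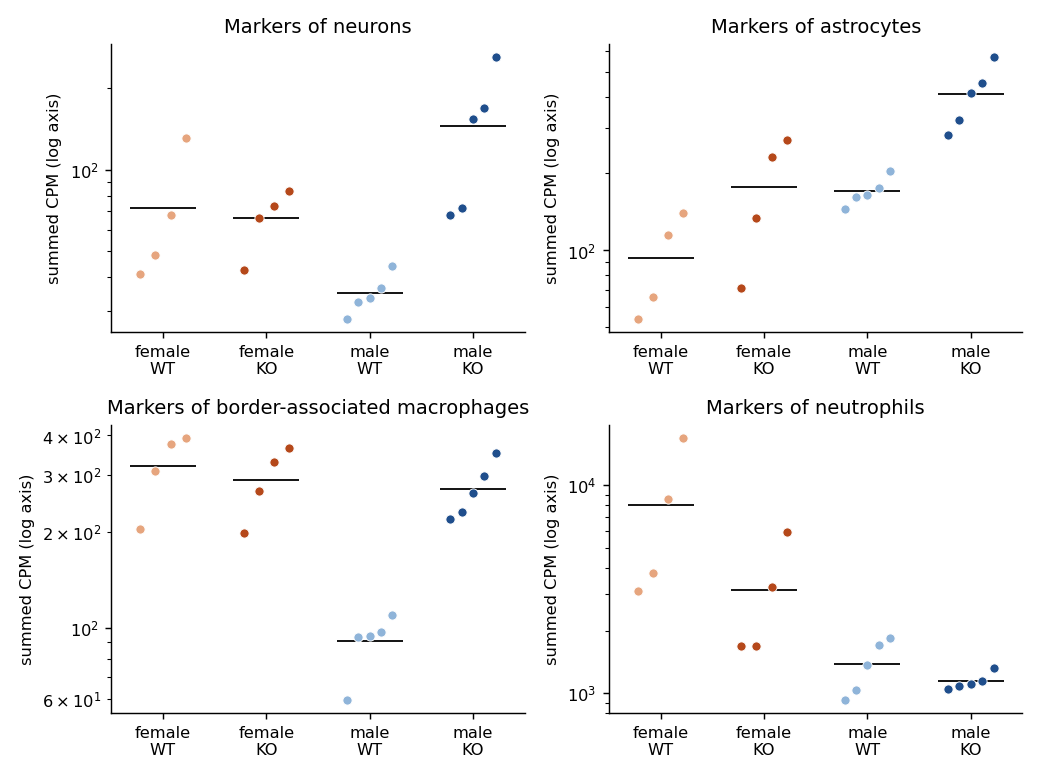
Summed CPM (log axis) of markers of neurons, astrocytes, border-associated macrophages and neutrophils in each library, by group, with 1 point per library and a bar at the group mean. Male KO libraries lie above male WT libraries for neurons, astrocytes and border-associated macrophages, and female WT replicate 30 has the highest neutrophil sum, 16798 CPM.

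KO and WT males were compared next. Genes of astrocytes, neurons and myelinating cells were among those that rose. Slc1a2, the main glutamate transporter of astrocytes, rose by a log2 fold change of 4.25 ± 0.60, Mobp, a myelin protein, by 3.66 ± 0.52, Kif5a, a neuronal kinesin, by 3.56 ± 0.55, and Nrgn, a postsynaptic calmodulin-binding protein, by 3.33 ± 0.51. Mbp, a major myelin protein, went from 56.7 ± 19.5 CPM in WT to 388 ± 219 CPM in KO (log2 fold change 2.75 ± 0.34). Of the astrocyte markers 7 of 9 tested members rose and 0 fell (8 and 0 adjusted within the list). The astrocyte list had a camera adjusted p = 8.37e-13 and adjusted p = 0.0263 with an estimated correlation. Of the neuronal markers 6 of 8 tested members rose and 0 fell (7 and 0 adjusted within the list). The neuronal list had a camera adjusted p = 1.59e-08 and adjusted p = 0.0881 with an estimated correlation. Of the oligodendrocyte lineage markers 4 of 8 tested members rose and 1 fell (5 and 1 adjusted within the list). The oligodendrocyte lineage list had a camera adjusted p = 0.000933 and adjusted p = 0.0941 with an estimated correlation. The 1 that fell was Cnp (-0.52 ± 0.12), a myelin enzyme also expressed by other cells. Male KO replicates 6, 9 and 17 held the most neural transcripts, and among the genes named here Camk2a, a neuronal kinase (2.06 ± 0.41), and Kif5a no longer passed without these 3 libraries (log2 fold changes 0.58 and 2.17).

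Border-associated macrophage genes also rose in male KO. Cbr2, a carbonyl reductase that marks these cells, was at 42.0 ± 6.71 CPM in KO and 7.44 ± 2.11 CPM in WT, 5.45-fold higher (log2 fold change 2.45 ± 0.25, edgeR adjusted p = 4.47e-06). The chemokine Pf4 rose from 20.3 ± 4.48 to 72.3 ± 17.7 CPM (1.84 ± 0.22), the lectin Cd209f by 3.17 ± 0.39 and the membrane protein Ms4a7 by 1.81 ± 0.30. Of the list 8 of 15 tested members rose and 0 fell (12 and 0 adjusted within the list). The border-associated macrophage list had a camera adjusted p = 4.25e-18 and adjusted p = 0.0129 with an estimated correlation. The calls of these 4 genes held in each of 26 alternative fits. Of the endothelial and mural markers 0 of 4 tested members rose and 1 fell (1 and 1 adjusted within the list). The endothelial and mural list had a camera adjusted p = 0.426 and did not pass. Their median log2 fold change of -0.31 and mean of 0.15 differed in sign. Of the monocyte markers 0 of 10 tested members rose and 0 fell. The monocyte list had a camera adjusted p = 0.854 and did not pass. Of the neutrophil markers 0 of 12 tested members rose and 0 fell. The neutrophil list had a camera adjusted p = 0.140 and did not pass. Erythroid markers were higher as a list, where 0 of 4 tested members rose and 0 fell (4 and 0 adjusted within the list). The erythroid list had a camera adjusted p = 0.0101 and adjusted p = 0.342 with an estimated correlation.

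Of microglial genes, the fractalkine receptor Cx3cr1 fell from 2881 ± 416 CPM in WT to 1301 ± 327 in male KO (log2 fold change -1.15 ± 0.16, edgeR adjusted p = 0.000136). Whether its locus was altered is unknown. Ltc4s, a leukotriene synthase, fell by -0.76 ± 0.11 and the secreted protein Olfml3 by -0.42 ± 0.11. Of the microglial identity genes 0 of 35 tested members rose and 3 fell (0 and 6 adjusted within the list). The list had a camera adjusted p = 0.000172 and adjusted p = 0.0129 with an estimated correlation. Of disease-associated microglia genes 4 of 29 tested members rose and 1 fell (7 and 1 adjusted within the list), with the lipid carrier Apoe (1788 ± 201 to 3727 ± 493 CPM, 1.06 ± 0.16), the growth factor Igf1 (2.53 ± 0.36) and the receptor Axl (0.63 ± 0.16) higher and Cst7, an inhibitor of lysosomal cathepsins, lower (-1.19 ± 0.21). Apoe is also expressed by astrocytes and border-associated macrophages, whose markers rose in the same libraries. The disease-associated list did not pass (camera adjusted p = 0.0676).

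Some cell cycle genes and p53 targets rose in male KO. Cdkn1a, the p53-induced cell cycle inhibitor p21, was at 128 ± 23.4 CPM in KO and 52.9 ± 8.04 CPM in WT, 2.43-fold higher (log2 fold change 1.28 ± 0.14, edgeR adjusted p = 9.23e-06). Phlda3, another p53 target, rose by 2.35 ± 0.42. Of the p53 targets 4 of 25 tested members rose and 0 fell (5 and 1 adjusted within the list). The p53 targets list had a camera adjusted p = 0.0676 and did not pass. Mcm2 and Mcm5, subunits of the replicative helicase, rose by 0.94 ± 0.18 and 0.96 ± 0.19. Of the proliferation list 5 of 26 tested members rose and 0 fell (8 and 0 adjusted within the list). The proliferation list had a camera adjusted p = 5.28e-08 and adjusted p = 0.0319 with an estimated correlation.

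Interferon-induced genes were higher as a list in male KO, where 4 of 37 tested members rose and 0 fell (5 and 0 adjusted within the list). The interferon list had a camera adjusted p = 0.00331 and adjusted p = 0.342 with an estimated correlation. Oas2, an antiviral oligoadenylate synthase, rose by 1.35 ± 0.25 and Ifit3 by 0.70 ± 0.16. Of the inflammatory cytokines 6 of 30 tested members rose and 0 fell (6 and 2 adjusted within the list). The inflammatory cytokine list had a camera adjusted p = 0.0614 and did not pass. Among those that rose were the chemokines Ccl7 (1.82 ± 0.38) and Ccl9 (0.74 ± 0.16), which attract myeloid cells. Of the cytosolic ribosomal protein genes 0 of 78 tested members rose and 2 fell (0 and 1 adjusted within the list). The ribosomal protein list had a camera adjusted p = 0.00263 and adjusted p = 0.739 with an estimated correlation. Its median log2 fold change was -0.17. Gapdh, a glycolytic enzyme with many pseudogenes that can share its reads, fell by -2.59 ± 0.66, but its WT mean rested on replicate 13 with 208 CPM, and without that library the log2 fold change was -0.59 (edgeR adjusted p = 0.226, the highest of 25 alternatives, where the lowest was 1.25e-16). The growth hormone transcript Gh had the largest fitted rise (7.75 ± 1.82), carried by KO replicate 6 with 117 CPM, and it no longer passed without KO replicates 6, 9 and 17. Beyond the lists, Mfsd13a, a putative transporter, fell by -1.996 ± 0.22 and the zinc finger gene Zfp580 by -1.83 ± 0.17.

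In all, 683 of 10948 tested genes passed between KO and WT in males (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 369 higher and 314 lower, and 293 of them by at least 2-fold. The count was 222 on read counts without UMI correction, 1145 with the male libraries fitted alone and 196 without KO replicates 6, 9 and 17. Within the 7 male libraries of the lowest reads-per-UMI range, 940 genes passed, of which 540 were shared with the fit of all libraries.

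KO and WT females were compared in the same fit. The monocyte and neutrophil lists were lower. Ly6c2, a marker of inflammatory monocytes, was at 12.2 ± 2.48 CPM (n = 4) in KO and 68.2 ± 35.3 CPM (n = 4) in WT, 5.15-fold lower (log2 fold change -2.37 ± 0.40, edgeR adjusted p = 0.00497). The monocyte protease Napsa fell by -1.61 ± 0.29 and the calcium-binding protein S100a6 by -1.72 ± 0.34. Of the monocyte markers 0 of 10 tested members rose and 5 fell (0 and 9 adjusted within the list). The monocyte list had a camera adjusted p = 1.69e-11 and adjusted p = 0.0746 with an estimated correlation. Of the neutrophil markers 0 of 12 tested members rose and 7 fell (0 and 10 adjusted within the list). The neutrophil list had a camera adjusted p = 6.06e-09 and adjusted p = 0.198 with an estimated correlation. The granule protein Ltf (-2.55 ± 0.58) and the iron-binding protein Lcn2 (-2.31 ± 0.55) were among those that fell. The highest neutrophil sum belonged to female WT replicate 30.

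Lysozyme, Lyz2, fell from 1998 ± 592 to 884 ± 136 CPM in females (-1.17 ± 0.18) and Cst7 from 34.998 ± 8.70 to 15.2 ± 5.38 CPM (-1.41 ± 0.26). Of disease-associated microglia genes 0 of 29 tested members rose and 5 fell (1 and 7 adjusted within the list). The disease-associated microglia list had a camera adjusted p = 0.00259 and adjusted p = 0.198 with an estimated correlation. The class II antigen presentation genes Cd74, the invariant chain (-1.03 ± 0.26), and H2-Ab1 (-0.84 ± 0.20) fell, and of their list 0 of 23 tested members rose and 5 fell (0 and 5 adjusted within the list). The antigen presentation list had a camera adjusted p = 0.107 and did not pass. It had a median of 0.00 and a mean of -0.18 on the log2 scale. Of the microglial identity genes 0 of 35 tested members rose and 1 fell (0 and 1 adjusted within the list). The microglial identity list had a camera adjusted p = 0.637 and did not pass. Olfml3 was the gene that fell (-0.52 ± 0.13). Lyz2 and class II genes are also expressed by monocytes, whose list was lower in the same libraries.

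Immediate early genes, which respond to activation and tissue dissociation, were higher as a list in female KO. The transcription factor Jun was at 959 ± 248 CPM in KO and 414 ± 85.6 CPM in WT, 2.32-fold higher (1.21 ± 0.18, edgeR adjusted p = 0.00264). Egr1 rose by 1.12 ± 0.21 and Zfp36, an RNA-binding protein that destabilises cytokine transcripts, by 1.29 ± 0.27. Of the immediate early and dissociation list 5 of 29 tested members rose and 0 fell (15 and 0 adjusted within the list). The list had a camera adjusted p = 1.92e-11 and adjusted p = 0.0799 with an estimated correlation.

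Cdkn1a rose in females from 55.8 ± 9.22 to 119.6 ± 17.9 CPM, 2.17-fold (1.12 ± 0.18, edgeR adjusted p = 0.00295), and Chek2, a DNA damage checkpoint kinase, from 17.5 ± 3.46 to 41.2 ± 8.98 CPM (1.32 ± 0.21). Of the p53 targets 1 of 25 tested members rose and 0 fell (2 and 1 adjusted within the list). The p53 targets list had a camera adjusted p = 0.0317 and adjusted p = 0.278 with an estimated correlation. The helicase subunits Mcm2 (1.16 ± 0.23) and Mcm4 (1.53 ± 0.32) rose. Of the proliferation genes 3 of 26 tested members rose and 0 fell (3 and 0 adjusted within the list). The proliferation list had a camera adjusted p = 0.104 and did not pass. Hspb1, a small heat shock protein, had the largest rise by the naming rule (1.99 ± 0.52), a call that held in 10 of 25 alternative fits.

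Ribosomal protein genes were lower as a list in female KO. Rps14 went from 1976 ± 290.2 to 1132 ± 210.0 CPM (-0.80 ± 0.15) and Rpl28 by -0.76 ± 0.14. Of the list 0 of 78 tested members rose and 15 fell (0 and 32 adjusted within the list). The list had a camera adjusted p = 1.74e-19 and adjusted p = 0.198 with an estimated correlation. Their sum went with reads per UMI, at 72655 to 83449.7 CPM in the 4 libraries of the highest range, where KO replicate 33 held 80360, and at 44150.5 to 68753 CPM in the other 4 female libraries. With that range as a covariate the list passed (camera adjusted p = 7.01e-05). Outside that range the only female WT library was replicate 39, so this cannot decide. Nuclear genes of oxidative phosphorylation, with Ndufb7 of complex I lower by -0.80 ± 0.16, were lower as a list, where 0 of 79 tested members rose and 3 fell (0 and 3 adjusted within the list). The list had a camera adjusted p = 0.00265 and adjusted p = 0.417 with an estimated correlation. Mitochondrially encoded transcripts were lower as a list, where 0 of 6 tested members rose and 0 fell (0 and 1 adjusted within the list). The list had a camera adjusted p = 0.0124 and adjusted p = 0.404 with an estimated correlation. Female WT replicates 34 and 39 held the most of these transcripts (9191 and 4523 CPM), and without replicate 34 the list did not pass (camera adjusted p = 0.176). Of the X-linked female-biased genes 0 of 10 tested members rose and 0 fell. The list had a camera adjusted p = 0.0380 and adjusted p = 0.198 with an estimated correlation. It was lower in KO, and without KO replicate 33, whose sum of 119 CPM was the lowest among females, it did not pass (camera adjusted p = 0.203). Astrocyte and erythroid markers were higher as lists. Of the astrocyte markers 0 of 9 tested members rose and 0 fell. The list had a camera adjusted p = 0.00920 and adjusted p = 0.404 with an estimated correlation. Of the erythroid markers 0 of 4 tested members rose and 0 fell. The list had a camera adjusted p = 0.0286 and adjusted p = 0.404 with an estimated correlation. Neuronal (camera adjusted p = 0.875), oligodendrocyte lineage (camera adjusted p = 0.637) and border-associated macrophage markers (camera adjusted p = 0.845) did not pass. Median and mean log2 fold changes were 0.15 and 0.01 for neuronal markers, where the test pointed down, and -0.02 and 0.06 for border-associated macrophage markers.

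In females 293 of 10948 genes passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 93 higher and 200 lower, and 170 of them by at least 2-fold. The share of these that were higher was 31.7%, against 45.6% on read counts without UMI correction, 44.2% without KO replicate 7 and 21.6% with limma voom. The count was 0 with the female libraries fitted alone by edgeR, where 828 of 9188 genes had an unadjusted p under 0.05, while limma voom with library quality weights called 136 in the same libraries. Without female KO replicate 33 it was 680, without KO replicate 16, 1 or 7 it was 110, 116 or 95, and without WT replicate 34 or 30 it was 150 or 71. With the reads-per-UMI range as a covariate it was 100, of which 51 were shared with the fit without it.

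Averaging the female and male KO effects with equal weight asked which genes moved with KO on average. Cdkn1a rose by 1.20 ± 0.11 (edgeR adjusted p = 2.04e-06) and Mcm2 by 1.05 ± 0.14, while Cst7 fell by -1.30 ± 0.17, Mfsd13a by -1.69 ± 0.18 and Cx3cr1 by -0.83 ± 0.12, and all 5 calls held in each of 32 alternative fits. Of the averaged effects, 1040 genes passed (edgeR quasi-likelihood test, Benjamini-Hochberg), 478 higher and 562 lower, 265 of them by at least 2-fold, with 1584 genes without female KO replicate 33 and 480 on read counts without UMI correction. Ribosomal protein genes were lower, where 0 of 78 tested members rose and 19 fell (0 and 29 adjusted within the list). The ribosomal protein list had a camera adjusted p = 3.56e-13 and adjusted p = 0.245 with an estimated correlation. Immediate early genes and inflammatory cytokines were higher as lists in this average. Of the immediate early genes 6 of 29 tested members rose and 0 fell (12 and 0 adjusted within the list). The immediate early list had a camera adjusted p = 8.77e-06 and adjusted p = 0.211 with an estimated correlation. In males alone 1 of 29 tested members rose and 0 fell (0 and 0 adjusted within the list), and the list did not pass (camera adjusted p = 0.488). Of the cytokines 7 of 30 tested members rose and 0 fell (7 and 1 adjusted within the list). The inflammatory cytokine list had a camera adjusted p = 0.0253 and adjusted p = 0.252 with an estimated correlation. In the latter Ccl3, a chemokine, rose by 0.75 ± 0.16 and Tnf by 0.66 ± 0.17. Proliferation genes and p53 targets were higher as lists. Of the proliferation genes 5 of 26 tested members rose and 0 fell (6 and 0 adjusted within the list). The proliferation list had a camera adjusted p = 1.81e-05 and adjusted p = 0.211 with an estimated correlation. Of the p53 targets 4 of 25 tested members rose and 1 fell (4 and 1 adjusted within the list). The p53 targets list had a camera adjusted p = 0.0163 and adjusted p = 0.245 with an estimated correlation. The 1 that fell was Trp53 itself (-0.43 ± 0.09).

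In the averaged effect astrocyte, border-associated macrophage, neuronal, oligodendrocyte lineage and erythroid markers were higher as lists, and neutrophil and monocyte markers lower as lists, none of them with an estimated correlation. In females alone the border-associated macrophage, neuronal and oligodendrocyte lineage lists did not pass, and in males alone the neutrophil and monocyte lists did not. Of the astrocyte markers 7 of 9 tested members rose and 0 fell (9 and 0 adjusted within the list). The astrocyte list had a camera adjusted p = 2.87e-09 and adjusted p = 0.197 with an estimated correlation. Of the border-associated macrophage markers 7 of 15 tested members rose and 0 fell (10 and 0 adjusted within the list). The border-associated macrophage list had a camera adjusted p = 9.62e-08 and adjusted p = 0.197 with an estimated correlation. Of the neuronal markers 2 of 8 tested members rose and 0 fell (5 and 0 adjusted within the list). The neuronal list had a camera adjusted p = 0.00134 and adjusted p = 0.255 with an estimated correlation. Of the oligodendrocyte lineage markers 3 of 8 tested members rose and 1 fell (4 and 1 adjusted within the list). The oligodendrocyte lineage list had a camera adjusted p = 0.0171 and adjusted p = 0.245 with an estimated correlation. Of the erythroid markers 0 of 4 tested members rose and 0 fell (4 and 0 adjusted within the list). The erythroid list had a camera adjusted p = 0.00221 and adjusted p = 0.245 with an estimated correlation. Of the neutrophil markers 0 of 12 tested members rose and 8 fell (0 and 10 adjusted within the list). The neutrophil list had a camera adjusted p = 8.77e-06 and adjusted p = 0.245 with an estimated correlation. Of the monocyte markers 0 of 10 tested members rose and 4 fell (0 and 9 adjusted within the list). The monocyte list had a camera adjusted p = 3.71e-05 and adjusted p = 0.211 with an estimated correlation.

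The CHD remodelers were lower as a list in the averaged effect, and Chd8 was the 1 that fell. Of the CHD remodelers 0 of 9 tested members rose and 1 fell (0 and 1 adjusted within the list). The CHD remodeler list had a camera adjusted p = 0.0294 and adjusted p = 0.245 with an estimated correlation. It did not pass in males (camera adjusted p = 0.0614) or females (camera adjusted p = 0.107). Of the microglial identity genes 0 of 35 tested members rose and 4 fell (0 and 4 adjusted within the list). The microglial identity list had a camera adjusted p = 0.0511 and did not pass.

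The female and male effects, which share no library, were then set against each other. Of 95 genes called in both sexes, 93 moved in the same direction, 48 higher and 45 lower, where 3.13 and 5.74 would be found by independent lists. They included Cdkn1a, Chek2 (1.32 ± 0.21 in females and 1.27 ± 0.15 in males), Mcm2, Mcm6 (0.74 ± 0.19 and 0.59 ± 0.15) and Pdcd1, an inhibitory receptor better known from T cells (1.36 ± 0.29 and 1.49 ± 0.20), among those that rose, and Cst7, Mfsd13a, Olfml3 and Ndufb7 among those that fell. The 2 that went in opposite directions were H2-Aa, a class II antigen presentation gene (-0.74 ± 0.20 in females and 0.67 ± 0.17 in males), and Axl (-0.75 ± 0.18 and 0.63 ± 0.16). The female value of H2-Aa and the male values of Chek2, Mcm6 and Pdcd1 lie outside the rule by which genes were named and were chosen after they were seen. Across all 10948 genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.326 and Spearman's rho = 0.349. Of the 683 male calls 86.7% had the same sign in females, and of the 293 female calls 83.3% had the same sign in males, against 62.4% of all genes. The correlation was 0.210 on read counts without UMI correction.

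**Figure D4:**
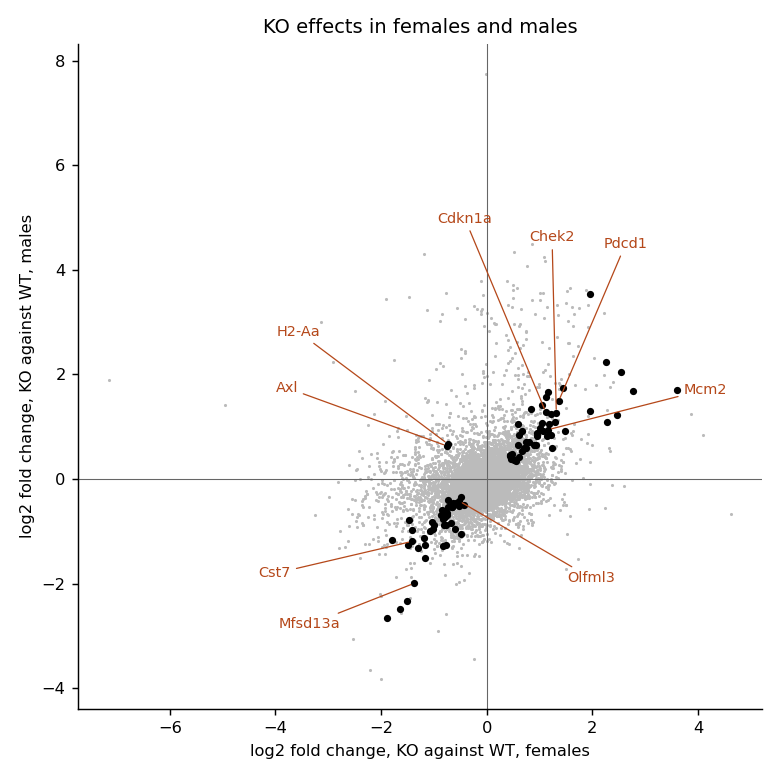
Log2 fold change between KO and WT in females (x axis) and in males (y axis) for each of 10948 tested genes, in grey, with the 95 genes called in both sexes in black and 9 named genes labelled. Of the 95 genes, 93 lie in the quadrants of equal sign, and Axl and H2-Aa lie to the left of 0 in females and above 0 in males.

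Whether the KO effect differed between females and males was tested by the interaction, given as the female minus the male effect. The difference for Cbr2 was -2.86 ± 0.36 (edgeR adjusted p = 0.000835), as this gene rose in males while in females it was at 46.3 ± 4.93 CPM in KO and 64.7 ± 27.1 CPM in WT. Pf4 (-1.94 ± 0.32), Cd209f (-3.18 ± 0.59) and Pla2g7, a lipoprotein-associated phospholipase (-2.82 ± 0.49), differed in the same direction, and male WT was the lowest of the 4 groups for each. Apoe differed by -1.37 ± 0.24, Axl by -1.39 ± 0.24, Lyz2 by -1.36 ± 0.24, H2-Aa by -1.41 ± 0.26 and H2-Eb1 by -1.43 ± 0.30. In the other direction Hist1h1c, a linker histone, differed by 1.66 ± 0.24, with 215 ± 41.5 CPM in male WT and 89.7 ± 11.2 in male KO, and the immediate early genes Jun and Egr1 differed by 1.21 ± 0.24 and 1.27 ± 0.27. The border-associated macrophage list had a camera adjusted p = 6.21e-19 and adjusted p = 0.00604 with an estimated correlation. The microglial identity list had a camera adjusted p = 2.60e-05 and adjusted p = 0.00604 with an estimated correlation. The disease-associated microglia list had a camera adjusted p = 5.44e-07 and adjusted p = 0.0300 with an estimated correlation. The monocyte list had a camera adjusted p = 1.46e-08 and adjusted p = 0.0451 with an estimated correlation.

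Of all tested genes 26 differed between sexes (edgeR quasi-likelihood test, Benjamini-Hochberg), 5 with a higher and 21 with a lower female effect, and 959 had an unadjusted p under 0.05. The count moved with single libraries. It was 46, 16, 15 and 11 without female KO replicates 33, 16, 1 and 7, and 13, 13, 84 and 2 without female WT replicates 34, 39, 31 and 30. Without male KO replicates 6 and 17 it was 11 and 12, and without male WT replicates 13, 10, 11 and 14 it was 12, 16, 16 and 11. Cbr2 was called in all 32 alternative fits and Hist1h1c in 30.

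WT males and females were compared as the baseline of sex. Xist, the X-inactivation RNA, was at 79.0 ± 24.5 CPM in female WT and 0.472 ± 0.325 CPM in male WT (log2 fold change, male minus female, -7.18 ± 0.41). The antigen presentation list was lower in males, with Cd74 at 502 ± 128 CPM against 2754 ± 527 CPM in females (-2.45 ± 0.25) and H2-Eb1 lower by -1.98 ± 0.21. Of the antigen presentation list 0 of 23 tested members were higher and 7 lower in males (0 and 7 adjusted within the list). The antigen presentation list had a camera adjusted p = 4.42e-07 and adjusted p = 0.0242 with an estimated correlation. The antiviral gene Ifitm3 was lower by -2.80 ± 0.31, and of the interferon list 0 of 37 tested members were higher and 16 lower in males (0 and 19 adjusted within the list). The interferon list had a camera adjusted p = 3.13e-08 and adjusted p = 0.0362 with an estimated correlation. Cbr2 (-3.03 ± 0.27), Lyz2 (-1.84 ± 0.17) and Apoe (-1.54 ± 0.17) were lower in male WT. Of the border-associated macrophage markers 0 of 15 tested members were higher and 11 lower in males (0 and 13 adjusted within the list). The border-associated macrophage list had a camera adjusted p = 6.13e-14 and adjusted p = 0.0142 with an estimated correlation. Of the monocyte markers 0 of 10 tested members were higher and 9 lower in males (0 and 10 adjusted within the list). The monocyte list had a camera adjusted p = 5.01e-16 and adjusted p = 0.0113 with an estimated correlation. Of the neutrophil markers 0 of 12 tested members were higher and 12 lower in males (0 and 12 adjusted within the list). The neutrophil list had a camera adjusted p = 8.62e-13 and adjusted p = 0.0547 with an estimated correlation.

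Immediate early genes were higher in male WT as a list. The heat shock genes Hspa1b (3.50 ± 0.56) and Hspa1a (3.05 ± 0.47) and the transcription factors Junb (2.26 ± 0.27) and Jun (1.84 ± 0.18) were higher, and of their list 16 of 29 tested members were higher and 3 lower in males (18 and 4 adjusted within the list). The immediate early list had a camera adjusted p = 1.44e-13 and adjusted p = 0.0216 with an estimated correlation. Of the microglial identity genes 10 of 35 tested members were higher and 2 lower in males (12 and 2 adjusted within the list). The microglial identity list had a camera adjusted p = 0.00160 and adjusted p = 0.0216 with an estimated correlation. Genes of disease-associated microglia, ribosomal proteins, oxidative phosphorylation, mitochondrial transcripts, proliferation, neurons and female-biased X-linked genes were lower as lists. Of the disease-associated microglia genes 3 of 29 tested members were higher and 10 lower in males (3 and 11 adjusted within the list). The list had a camera adjusted p = 4.56e-05 and adjusted p = 0.0524 with an estimated correlation. Of the ribosomal protein genes 0 of 78 tested members were higher and 53 lower in males (1 and 62 adjusted within the list). The list had a camera adjusted p = 6.29e-20 and adjusted p = 0.115 with an estimated correlation. Their sum went with reads per UMI here too, also within male WT. With the range as a covariate the list passed (camera adjusted p = 0.000663), but only female WT replicate 39 shared a range with males. Of the oxidative phosphorylation genes 1 of 79 tested members were higher and 24 lower in males (1 and 32 adjusted within the list). The list had a camera adjusted p = 8.86e-06 and adjusted p = 0.273 with an estimated correlation. Of the mitochondrial transcripts 0 of 6 tested members were higher and 5 lower in males (0 and 6 adjusted within the list). The mitochondrial transcript list had a camera adjusted p = 0.00427 and adjusted p = 0.344 with an estimated correlation. Of the proliferation genes 1 of 26 tested members were higher and 11 lower in males (1 and 13 adjusted within the list). The proliferation list had a camera adjusted p = 0.000237 and adjusted p = 0.120 with an estimated correlation. Of the neuronal markers 0 of 8 tested members were higher and 2 lower in males (0 and 2 adjusted within the list). The neuronal list had a camera adjusted p = 0.0395 and adjusted p = 0.443 with an estimated correlation. Of the X-linked genes 0 of 10 tested members were higher and 3 lower in males (0 and 5 adjusted within the list). The X-linked list had a camera adjusted p = 3.63e-06 and adjusted p = 0.0113 with an estimated correlation.

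Of 10948 genes 1892 passed (edgeR quasi-likelihood test, Benjamini-Hochberg), 760 higher and 1132 lower in males. This count was 1092 without female WT replicate 30, 271 with the reads-per-UMI range as a covariate and 292 without the 4 libraries of the highest range, which hold 3 of the 4 female WT libraries.

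KO males and females were then compared. Xist (-6.95 ± 0.40, male minus female) and Rlim, an X-linked ubiquitin ligase (-3.29 ± 0.33), were lower in males. Of X-linked female-biased genes 0 of 10 tested members were higher and 2 lower in males (0 and 6 adjusted within the list). The X-linked list had a camera adjusted p = 6.65e-05 and adjusted p = 0.175 with an estimated correlation. Cx3cr1 was lower in male KO (-0.93 ± 0.17), as were B2m, the light chain of class I molecules (-1.004 ± 0.18), and the cytokine Il1b (-1.35 ± 0.23). Of the antigen presentation genes 0 of 23 tested members were higher and 4 lower in males (0 and 11 adjusted within the list). The antigen presentation list had a camera adjusted p = 0.000502 and adjusted p = 0.255 with an estimated correlation. Of the interferon genes 0 of 37 tested members were higher and 4 lower in males (0 and 8 adjusted within the list). The interferon list had a camera adjusted p = 0.000112 and adjusted p = 0.255 with an estimated correlation. Of the monocyte markers 0 of 10 tested members were higher and 5 lower in males (0 and 5 adjusted within the list). The monocyte list had a camera adjusted p = 6.65e-05 and adjusted p = 0.255 with an estimated correlation. Of the neutrophil markers 0 of 12 tested members were higher and 5 lower in males (0 and 10 adjusted within the list). The neutrophil list had a camera adjusted p = 6.48e-07 and adjusted p = 0.255 with an estimated correlation. The ribosomal protein Rps15a was lower by -3.04 ± 0.48. Of the ribosomal protein genes 0 of 78 tested members were higher and 14 lower in males (0 and 26 adjusted within the list). The ribosomal protein list had a camera adjusted p = 1.78e-08 and adjusted p = 0.497 with an estimated correlation. Of the proliferation genes 1 of 26 tested members were higher and 2 lower in males (1 and 4 adjusted within the list). The proliferation list had a camera adjusted p = 0.0322 and adjusted p = 0.510 with an estimated correlation.

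Higher in male KO than in female KO were Hspa1b (2.45 ± 0.47), the chaperone Hspa5 (1.22 ± 0.22), Mobp (2.09 ± 0.53) and Mbp (1.76 ± 0.37). Neural markers were higher as lists. Of the astrocyte markers 5 of 9 tested members were higher and 0 lower in males (7 and 0 adjusted within the list). The astrocyte list had a camera adjusted p = 3.95e-05 and adjusted p = 0.255 with an estimated correlation. Of the oligodendrocyte lineage markers 3 of 8 tested members were higher and 0 lower in males (4 and 0 adjusted within the list). The oligodendrocyte lineage list had a camera adjusted p = 0.0252 and adjusted p = 0.290 with an estimated correlation. Of the neuronal markers 1 of 8 tested members were higher and 0 lower in males (2 and 0 adjusted within the list). The neuronal list had a camera adjusted p = 0.0322 and adjusted p = 0.635 with an estimated correlation. Without male KO replicates 6, 9 and 17 the neuronal list turned direction and did not pass (camera adjusted p = 0.847). Of the immediate early genes 6 of 29 tested members were higher and 1 lower in males (11 and 2 adjusted within the list). The immediate early list had a camera adjusted p = 7.43e-05 and adjusted p = 0.255 with an estimated correlation. Of the stress response genes 3 of 19 tested members were higher and 1 lower in males (5 and 1 adjusted within the list). The stress response list had a camera adjusted p = 0.0342 and adjusted p = 0.290 with an estimated correlation. Of 10948 genes 777 passed (edgeR quasi-likelihood test, Benjamini-Hochberg), 310 higher and 467 lower in males. The count was 1782, 362 and 207 without female KO replicates 16, 1 and 7, 507, 467 and 456 without male KO replicates 6, 17 and 40, and 104 without male KO replicates 6, 9 and 17 together. Without a filter on low counts 1354 genes passed, and the share that was higher in males went from 39.9% to 51.5%.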

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

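The tests of explanations given here for 3 patterns were chosen only after the results were seen, as were the fits that use the reads-per-UMI range or leave out more than 1 library.

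Some libraries lay far from the others of their group, by the gap to the nearest library divided by the whole range (Dixon's ratio). Chance alone marks about 1 in 20 groups. Of 68 groups over per-library measures 8 held such a library, of 72 groups over the genes with group means in the text 4, and of 984 groups over all named genes 71, or 7.22%. Reads per UMI stood at 2.96 in female WT replicate 39, where the nearest library had 6.62, and at 2.94 in male KO replicate 9, where the nearest had 1.89. Female KO replicate 33 held 9.18 CPM of Ddx3y, 9.18 CPM of Uty and 2.29 CPM of Kdm5d, all Y-linked. Eif2s3y, also Y-linked, was at 0.758 CPM (1 UMI) in female WT replicate 39, where the others of that group held 0, and at 22.3 CPM in male WT replicate 37. Oligodendrocyte lineage markers summed to 1423 CPM in female WT replicate 39, the lowest of that group. Gapdh was at 208 CPM in male WT replicate 13, where the nearest library had 14.5 CPM. The growth hormone transcript Gh was at 117 CPM in male KO replicate 6, where the nearest had 8.96 CPM, and at 0.501 CPM in male WT replicate 10, where the others held 0. Mbp was at 91.5 CPM in male WT replicate 11.

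The KO effect differed between sexes for 26 genes by the interaction test in edgeR, given as the female minus the male log2 effect. It was lower in females for the macrophage genes Cbr2 (-2.86 ± 0.36), Pf4 (-1.94 ± 0.32), Cd209f (-3.18 ± 0.59), Pla2g7 (-2.82 ± 0.49), Apoe (-1.37 ± 0.24), Axl (-1.39 ± 0.24), Lyz2 (-1.36 ± 0.24), Napsa (-1.90 ± 0.39), Ifitm2 (-2.36 ± 0.48), Plbd1 (-1.69 ± 0.30), H2-Aa (-1.41 ± 0.26) and H2-Eb1 (-1.43 ± 0.30). It was also lower for Olfm1 (-2.99 ± 0.52), Hpca (-4.03 ± 0.72), Cyfip2 (-3.41 ± 0.71) and Sept3 (-4.32 ± 0.92), which neurons express, and for Fxyd5 (-1.60 ± 0.34), Crip1 (-1.55 ± 0.33), Rasgrp4 (-1.36 ± 0.28), Pkmyt1 (-1.30 ± 0.28) and the gene ENSMUSG00002075680, which has no symbol here (-9.05 ± 1.86, a size that depends on the prior count, as 3 of 4 female KO libraries held 0). It was higher in females for Hist1h1c (1.66 ± 0.24), Jun (1.21 ± 0.24), Egr1 (1.27 ± 0.27), Socs3 (1.05 ± 0.22) and Sumo3 (0.80 ± 0.16).

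Of the lists, 15 differed between sexes in the KO effect by limma camera, and 4 of them also with an estimated correlation. The median difference, female minus male on the log2 scale, was -1.50 for border-associated macrophages, -1.70 for monocytes, -0.22 for disease-associated microglia and 0.29 for microglial identity, which are those 4. It was -2.14 for neurons, -1.43 for astrocytes, -0.97 for oligodendrocyte lineage, -1.48 for neutrophils and -2.02 for mitochondrially encoded transcripts. Immediate early genes had 0.68, ribosomal proteins -0.29, oxidative phosphorylation -0.21, interferon genes -0.17, antigen presentation -0.0299 and proliferation -0.45, which turned direction without the highest reads-per-UMI range (camera adjusted p = 0.644).

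Neural transcripts were higher in male KO than in male WT, with a median log2 fold change of 2.06 over the neuronal, astrocyte and oligodendrocyte lineage members. A lower share of microglia would raise markers of all other cells alike. The 22 monocyte and neutrophil members had a median of -0.34 (highest 0.29), but border-associated macrophage, erythroid and lymphocyte sums were higher. That cause stays open. Library pools of different reads per UMI are argued against, as all 3 neural lists passed among the 7 male libraries of the lowest range. Neural cells or their RNA carried through purification cannot be told apart from other causes. The 92% of 25 neural members that were higher only restates the pattern, and the labels do not say how microglia were purified. A difference in dissociation between preparations or in the KO brain itself was not tested.

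Border-associated macrophage transcripts were low in male WT, with Cbr2 at 5.01 to 10.7 CPM in its 5 libraries and at 27.5 to 89.8 CPM in all other libraries. Library pools of different reads per UMI are argued against, since the list passed among the male libraries of the lowest range (limma camera adjusted p = 8.87e-21). A different share of these macrophages among the collected cells cannot be told apart from a change of expression within the cells, as the share of the 15 tested members that were higher in male KO, 93.3%, only restates the pattern. The labels give no preparation day, and the preparation, genotype and sex stay open as sources.

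Female WT differed from the other groups in many genes, while 3 of its 4 libraries were of the highest reads-per-UMI range, which no male library reached. With that range as a covariate 11.5% of the calls between male and female WT (217 of 1892) were kept. For these calls as a whole, range and group cannot be told apart, as the design nearly confounds them. The same holds for the antigen presentation list, which passed with the range (limma camera adjusted p = 5.91e-09). Only female WT replicate 39 shared a range with males. Low depth of 2 female libraries is argued against as the source of the female KO calls, which numbered 462 without them against 293 with them. Sex, and the monocyte and neutrophil transcripts of female WT, stay open and were not tested.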

How the results depend on the processing

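The settings that use the reads-per-UMI range, leave out more than 1 library at once or use limma voom were chosen only after the results were seen, and the other settings were planned. No paired analysis was possible because the labels name no pairing or litter and every library has a replicate number of its own. The cause was not tested for the changes below, except where fewer libraries or a fold minimum reduce calls by construction.

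Direction was kept more often than the side of the threshold. Over 418 values of named genes, size factors of DESeq2 kept 404 and the read table without UMI correction 272 on their side, and the rest fell short of the threshold there without a change of direction. All 6 gene counts stayed within 1.5 times of their value with size factors of DESeq2 and with a stricter filter, and the split into higher and lower calls moved by less than 10 percentage points with those factors. Of the per-library sums, in males the oligodendrocyte lineage ratio of KO to WT was 1.27 on read counts and no longer passed (exact permutation test, adjusted p = 0.0794), while the lymphocyte ratio of 1.19 passed there (exact permutation test, adjusted p = 0.0317).

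Called genes, on read counts without UMI correction, numbered 136 for KO in females, 222 in males, 480 averaged, 10 for the difference between sexes, 1188 for sex in WT and 312 for sex in KO. Without a filter on low counts they numbered 532 in females, 238 for the difference and 1354 for sex in KO. With only the compared groups fitted, edgeR called 0 in females (25 without the 2 shallowest libraries), 1145 in males and 235 for sex in KO. Limma voom with weights called 136 in females. The range of replicate numbers as a covariate gave 93 in females, 43 for the difference and 1035 for sex in WT. All 4 female WT were numbered 30 or more, so it nearly followed genotype in females and sex in WT. In that order log2 of the total count gave 137, 41 and 825, and 1 surrogate variable 537, 63 and 1593. DESeq2 gave 74 for the difference. The share of calls that were higher moved from 40.2% to 19.9% for sex in WT with log2 of reads per UMI and from 39.9% to 17.0% for sex in KO with only those groups fitted. A 2-fold minimum left 170 in females, 293 in males, 265 averaged, 879 for sex in WT and 374 for sex in KO.

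The reads-per-UMI range as a covariate gave 100 called genes in females, 622 averaged, 271 for sex in WT and 326 for sex in KO. The log2 of reads per UMI gave 45, 562, 14 for the difference, 156 and 368. Without the 4 libraries of the highest range the counts were 104 in females, 1209 in males, 652 averaged and 292 for sex in WT, and without the 2 shallowest 462 in females. Without male KO replicates 6, 9 and 17 they were 196 in males, 1 for the difference and 104 for sex in KO. With limma voom and library quality weights over all libraries, 1622 were called in males and 1561 for sex in KO.

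Leaving out 1 library at a time gave 71 to 680 called genes in females, 484 to 665 in males, 776 to 1584 averaged, 2 to 84 for the difference, 1092 to 2087 for sex in WT and 207 to 1782 for sex in KO. The correlation of the female and male effects across genes was 0.289 to 0.369 in these fits and 0.210 on read counts.

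Of the lists called in females, in males, averaged, for the difference, for sex in WT and for sex in KO (11, 9, 13, 15, 14 and 12), an estimated correlation left 0, 4, 0, 4, 7 and 0. Fry called 6 in females and 5 for the difference, where log2 of reads per UMI left 8. Without single libraries the called lists numbered 7 to 13, 9 to 13, 11 to 15, 12 to 16, 13 to 14 and 9 to 13.

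Few values turned direction. The proliferation list turned in the difference without the highest range (camera adjusted p = 0.644), and the neuronal list for sex in KO without male KO replicates 6, 9 and 17 (camera adjusted p = 0.847). Chd8 between male and female WT, which passed in none of 24 alternatives, went to a log2 fold change of 0.000666 without a filter, 0.13 with the range, 0.0701 with log2 of reads per UMI and 0.22 without the highest range. Top2a turned to 0.51 without the highest range and Slc1a3 to -0.0931 with the range as a covariate for sex in WT, and Camk2a to -0.00777 for sex in KO without male KO replicates 6, 9 and 17. Depth was lowest in the female comparison, where replicate 33 of KO and 34 of WT held 435838 and 458075 UMIs.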

Other observations

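The test of called genes near Chd8 by Fisher's exact test was chosen only after the result was seen, as were the settings that use the reads-per-UMI range, and the other tests were set before their results were seen.

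Several lists were described in no comparison of KO with WT above. In males the TGF-beta list, with the receptor component Eng (-0.51 ± 0.12) lower, had a camera adjusted p = 0.0947, and 0 of 17 tested members rose and 2 fell (0 and 2 adjusted within the list). Of the cholesterol synthesis genes 0 of 14 tested members rose and 1 fell (0 and 1 adjusted within the list), the one being Pmvk, phosphomevalonate kinase (-1.08 ± 0.21), and the list did not pass (camera adjusted p = 0.295). Of the complement and phagocytosis genes 1 of 30 tested members rose and 1 fell (1 and 1 adjusted within the list), with Axl higher and its ligand Gas6 lower (-0.87 ± 0.17), and the list did not pass (camera adjusted p = 0.978). Aldoc, a glycolytic enzyme that is also abundant in astrocytes, rose by 3.43 ± 0.48 in males, and of the glycolysis genes 1 of 20 tested members rose and 1 fell (1 and 1 adjusted within the list), with a camera adjusted p = 0.978. Of the stress response genes 1 of 19 tested members rose and 2 fell (1 and 3 adjusted within the list), with the transcription factor Atf4 (-0.45 ± 0.11) and Nupr1 (-0.54 ± 0.12) lower and Creld2, an endoplasmic reticulum protein, higher (0.63 ± 0.12), and the list did not pass (camera adjusted p = 0.374). Of the lysosome and autophagy genes 0 of 36 tested members rose and 1 fell (0 and 1 adjusted within the list), with a camera adjusted p = 0.932, the one being the autophagy receptor Sqstm1 (-0.39 ± 0.09). Of the histone methyltransferase complexes and CTCF 0 of 29 tested members rose and 1 fell (1 and 2 adjusted within the list), with a camera adjusted p = 0.846, the one being Setd1a (-0.56 ± 0.11). Of the Wnt and beta-catenin targets 0 of 8 tested members rose and 0 fell, with a camera adjusted p = 0.978. Median and mean had different signs for complement (-0.02 and 0.00) and Wnt targets (0.05 and -0.02).

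In females none of these 8 lists passed either. The central complement component C3 fell (-2.08 ± 0.49) with Axl, and of its list 0 of 30 tested members rose and 2 fell (0 and 3 adjusted within the list), with a camera adjusted p = 0.318. The glucose transporter Slc2a3 fell (-1.50 ± 0.37), and of the glycolysis genes 0 of 20 tested members rose and 1 fell (0 and 1 adjusted within the list), with a camera adjusted p = 0.107. The autophagy gene Becn1 rose (0.69 ± 0.18), and of the lysosome and autophagy genes 1 of 36 tested members rose and 0 fell (2 and 0 adjusted within the list), with a camera adjusted p = 0.0579. Tgfbi, an extracellular matrix protein, fell (-0.59 ± 0.15), and of the TGF-beta list 0 of 17 tested members rose and 1 fell (0 and 1 adjusted within the list), with a camera adjusted p = 0.603. C3 held a call in 11 of 25 alternative fits, Slc2a3 in 8 of 25, Becn1 in 10 of 25 and Tgfbi in 11 of 25.

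Xist and the Y-linked Eif2s3y went with the labelled sex in all 18 libraries, with Xist at 22.9 to 103 CPM of the library total in females and 0 to 0.879 CPM in males. Ddx3y varied among males, at 25.3, 1.11, 28.7, 1.86 and 5.90 CPM in male KO replicates 36, 6, 9, 17 and 40 against 9.75 to 23.8 CPM in male WT, while Eif2s3y was at 7.41 to 17.9 CPM in male KO. The shallowest library, female KO replicate 33, held 4 UMIs of Ddx3y, 4 of Uty, 1 of Kdm5d and 0 of Eif2s3y among 435838, beside 10 of Xist. Its Ddx3y CPM lay above that of 3 male KO libraries and its Uty CPM above that of all males.

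Other divisions of the same libraries into groups of equal size were fitted to ask whether chance could give as many calls. For KO in females 2 of all 35 divisions gave at least the 293 genes of the real one, so chance is not excluded. The highest other, 709 genes, set the 4 libraries of the highest reads-per-UMI range against the rest, a structure of the samples, and with that range as a covariate the real contrast gave 100 genes. For KO in males 1 of 100 drawn divisions reached 683 genes, the real one (highest other 1), and for the averaged effect 1 of 100 reached 1040 (highest other 35), so chance is excluded for both. It is excluded for sex in WT, where 1 of 100 reached 1892 (highest other 538, with male WT replicate 11 beside the 4 female WT libraries), and for sex in KO, where 1 of 100 reached 777. The highest other there, 476, set female KO replicate 16 and male KO replicates 36, 6, 17 and 40 against the rest, which are the KO libraries of the lowest range. For the difference between sexes 3 of 100 reached 26 genes, the real one included. The highest other, 263, swapped KO libraries between sexes, so such divisions carry the sex effect and chance is not excluded. For the correlation of the female and male effects 1 of 100 reached the real 0.326 (others -0.350 to 0.280), so chance is not excluded.

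DNA from another strain can stay around a targeted gene after breeding. A hypothesis was that such DNA around Chd8 could account for the genes called in both sexes. For other loci, such as Cx3cr1 and its called neighbours, this was not tested. Within 10 Mb of Chd8 lay 4.30% of the 93 genes called in both sexes in the same direction (4 genes, exact 95% interval 1.18% to 10.6%). This was under the 5% bound set beforehand, but the upper limit lay above it, and the rule was changed after the value was seen. As 89 of the 93 lie elsewhere, changes within such DNA are argued against for most of them. Its effects on distant genes were not tested. For the 4 near genes, Fisher's exact p = 0.0240 against the 1.18% of tested genes that lie there (129 genes), but they form only 2 loci, so this hypothesis cannot be told apart from chance for them. They were Rabggta (0.47 ± 0.12 in females and 0.49 ± 0.10 in males), Adcy4 (2.53 ± 0.57 and 2.04 ± 0.41), Ripk3, a kinase of necroptosis (1.11 ± 0.29 and 1.56 ± 0.21), and Amer2 (1.45 ± 0.36 and 1.75 ± 0.26), all higher in KO in both sexes and, except Amer2 in females, chosen after their values were seen. In females the calls of Rabggta, Adcy4, Ripk3 and Amer2 held in 9 of 25, 12 of 22, 11 of 25 and 11 of 25 alternative fits.

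A second hypothesis was that genes called in the averaged KO effect lie next to each other on the chromosomes. It arose when some neighbouring genes were seen among the strongest calls, before the pairs were counted, so the test is not independent of those genes. Among 10904 placed genes, of which 1037 were called, 140 adjacent pairs were both called, against a mean of 98.2 and a maximum of 130 over 2000 shuffled gene orders (one-sided permutation test, p = 0.0005, the smallest these shuffles can give). Pairs that moved in the same direction numbered 77 (49.2 by shuffling) and pairs that moved in opposite directions 63 (49.0, one-sided permutation p = 0.0235), and 21 of the pairs overlap, where reads may be shared. Shared regulation of neighbours and counting of reads across gene ends could both give such pairs, and no test here separates them.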
